A study of Rattus norvegicus with 16 samples.

How the data were processed

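RNA levels were measured in 16 libraries of Rcho-1 cells, a rat trophoblast stem cell line derived from a choriocarcinoma. Poly-A RNA libraries were made with a TruSeq RNA kit, per the labels' protocols. The deposited table holds 1 RPKM value (reads scaled by transcript length in kilobases and by the mapped reads of the library) per transcript and library, computed by the authors, per the file headers. The genome build was Rnor_5.0, per the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here. No scaling beyond length and library total is recorded, and no strand setting is stated, so overlapping genes on opposite strands could not be separated.

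The table has 33349 rows under 26079 gene names, of which 4558 rows carry contig names in place of a gene symbol. A number at the end of each row name counts the transcripts of a gene. For each gene the row with the highest mean RPKM over all 16 libraries was used, and genes with a mean of at least 1 RPKM were tested, which left 9710. Gene names are those of the table. Older symbols of list members were looked up in a RefSeq table of the assembly GRCr8, which was also used for the order of neighbouring genes and for the spans of short genes, and no other coordinates were taken from it. A low value in the table need not mean low expression: Rpl8, a ribosomal protein gene, was listed at 2.12 RPKM in the day-4 controls beside 666 RPKM for Rpl3.

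Depth was recovered from the RPKM values, because the values of a row are whole multiples of what 1 read is worth in each library. For 18923 rows above 0 in at least 12 libraries, a row length was found that made the reads of all 16 libraries whole numbers within 0.0001. The scale of the totals rested on 15 of 78 short genes whose span in the RefSeq table gave the same total for day-4 control 1. The recovered totals ran from 33.1 to 56.7 M reads per library, and 1 RPKM stood for 33.1 to 56.7 reads per kilobase. No libraries were identical. Each library counted as 1 sample.

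Groups were taken from the sample titles and treatments: control or knockdown, at 4 or 10 days, with 4 libraries in each of the 4 groups. The description of each knockdown sample names a control shRNA, in conflict with its title and treatment, and the Satb1 level was therefore checked in every library. Values were analysed as log2(RPKM + 1), and every log2 change and fold below is on that scale, which understates the change of genes with low values. A model with a mean per group was fitted to all 16 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend). The contrasts were knockdown minus control at day 4, the same at day 10, the difference between these effects, and day-10 minus day-4 controls. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Satb1 and Satb2 were also tested by an exact two-sided permutation test, for which 4 against 4 libraries allow 70 splits. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, using numpy 2.4.6 and pandas 2.3.3.

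The design, the 20 gene lists, the rule for naming genes and the settings listed below were fixed before the data were examined. The lists held trophoblast stem (TS) state, prolactin family and trophoblast hormones, giant cell and invasive trophoblast, steroid hormone synthesis, syncytiotrophoblast and junctional zone, FGF and ERK response, BMP and TGF-beta response, DNA replication, mitosis, p53 and cell cycle arrest, interferon response, unfolded protein and integrated stress response, cholesterol synthesis, hypoxia and glycolysis, epithelial junction and keratin, imprinted genes of placenta, markers of fibroblasts, markers of endothelial and blood cells, ribosomal proteins, and housekeeping genes. They name 394 symbols, 384 of them distinct. Of the 394, 377 matched a gene name of the table, 5 matched through an older symbol, and 272 were tested. Counts of list members below are of tested members. These were 10 of 21 for prolactins, 17 of 24 for giant cells, 8 of 13 for steroid synthesis and 3 of 23 for interferon. For imprinted genes they were 6 of 18. Because the filter used the mean over all libraries, a gene low in the controls could enter through high values in the knockdown libraries. Lists were tested with limma camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists, then with an estimated correlation and with fry, whose directional p asks whether a list moved on balance without comparing it with other genes. The naming rule took Satb1 and Satb2, the 10 largest called increases and decreases at each day among genes with no overlap between the groups, the 5 largest in each direction for the other contrasts, and up to 4 members per list with the smallest p. Genes known only by a locus or clone number were not named.

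The method was tested on simulated data for the 9710 genes. The changed genes were drawn only from genes with higher levels in the day-4 controls. Errors were independent between genes, with the same spread in all groups. The shares below therefore do not cover genes with low values, unequal spread between days or genes that vary together. It recovered 70.1% of genes changed 1.5-fold and 100% of those changed 2-fold at day 4. The corresponding shares were 77.6% and 98.5% at day 10, and 46.1% and 95.3% for the difference between days. False calls made up 6.25%, 3.66% and 4.86% of the calls in these contrasts, and none was made for the controls, where no gene had been changed.

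Settings varied by plan were other pseudocounts, other filters on low values, 3 other scalings, no mean-variance trend, array weights, a replicate block, only the 8 libraries of a comparison, a 2-fold minimum, and leaving out each library in turn. Settings chosen after seeing the data were the sum of a gene's rows, every row tested, limma voom on the recovered reads, removal of each library's trend with row length, reads thinned to the lowest total, and leaving out day-4 control 3 and day-4 knockdown 4 together. Reads of near-identical paralogs, such as the prolactin, cathepsin and Ceacam families, may have been split or shared by the authors' counting, so the levels of single members are uncertain.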

Results

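Rcho-1 cells can be kept in a stem state or allowed to differentiate into trophoblast giant cells. The cells had been transduced with shRNAs against Satb1, which encodes a chromatin-organising DNA-binding protein, or with control shRNA, and were held in medium for the stem state. RNA was sequenced 4 days (called acute in the labels) or 10 days (called chronic) after transduction, with 4 control and 4 knockdown libraries at each day. The series title ties the study to the role of Satb1 in stem cell renewal. The recovered depth was 44.7 to 54.6 M reads in the day-4 controls, 50.7 to 56.7 M in the day-4 knockdown, 45.6 to 55.6 M in the day-10 controls and 33.1 to 50.4 M in the day-10 knockdown libraries. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The design names 2 shRNAs against Satb1 without saying which library received which. By chi-square per degree of freedom between libraries, day-10 knockdown 1 and 2 (9.29) and 3 and 4 (7.98) were closest. The other pairs of that group gave 27.9 to 38.2. In the day-10 controls, 1 and 4 (13.3) and 2 and 3 (19.99) were closest, against 31.1 to 67.6. The day-4 groups did not split this way. The 4 libraries of a day-10 group may thus be fewer than 4 independent samples. What the pairs reflect was not tested.

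The targeted gene was low in each library titled knockdown. At day 4, Satb1 stood at 121 ± 21.7 RPKM (SD, n = 4) in the controls and at 12.2 ± 1.78 RPKM in the knockdown libraries, so that 10.1% of the control level was left. At day 10 the levels were 121 ± 14.7 and 7.24 ± 2.12 RPKM, with 6.0% left. The lowest control library (89.4 RPKM, day-4 control 3) lay above the highest knockdown library (14.2 RPKM), and the exact permutation p was 0.0286 at each day, the smallest that 70 splits allow. A minor Satb1 transcript fell to 22.2% of its control level at day 4 and to 14% at day 10. Satb2, the close paralog of Satb1, was at 4.34 ± 0.922 RPKM in the controls and 4.03 ± 0.508 RPKM in the knockdown libraries at day 4 (exact permutation p = 0.571). At day 10 Satb2 fell from 4.63 ± 0.717 to 2.67 ± 0.584 RPKM (exact permutation p = 0.0286; limma, Benjamini-Hochberg adjusted p = 0.0018).

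**Figure D1:**
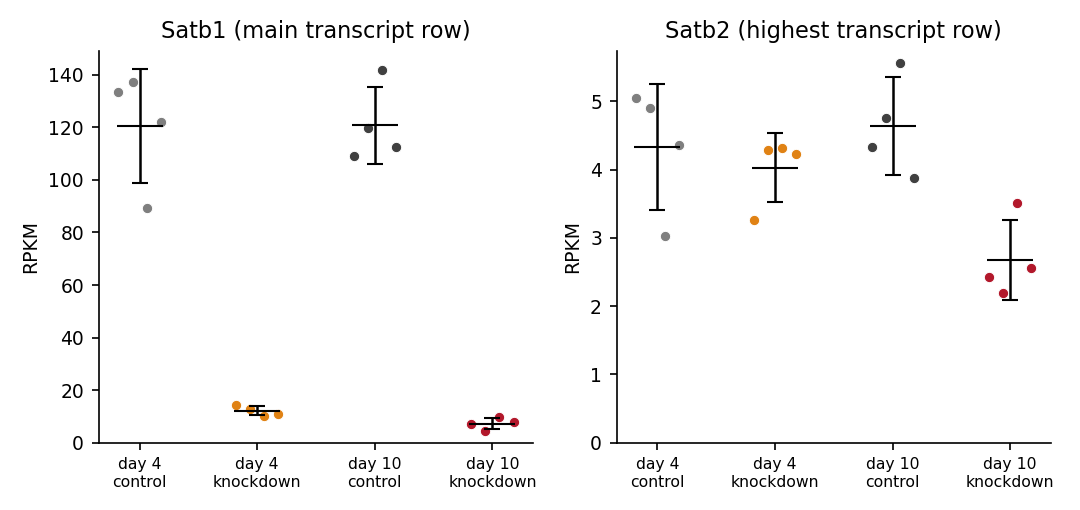
RPKM of the main Satb1 transcript (left) and of the higher Satb2 transcript (right) in the 16 libraries; points are libraries, bars are the mean and SD of 4. All 8 knockdown libraries lay at or below 14.2 RPKM of Satb1, and all 8 control libraries at or above 89.4 RPKM.

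The comparison at day 4 asked what changed soon after loss of Satb1. Genes known only by a locus or clone number were not ranked here, and 1 of them, LOC100366231, rose more than any named gene (log2 change 2.15). The largest named increase was that of Hspb1, a small heat shock protein gene, from 4.70 ± 1.61 to 19.7 ± 4.66 RPKM (SD, n = 4; log2 change 1.87 ± 0.20 SE; limma, Benjamini-Hochberg adjusted p = 1.59e-05). Krt7, a keratin of simple epithelia, rose from 20.7 ± 1.87 to 60.2 ± 11.6 RPKM, Plet1 from 110 ± 16.1 to 277 ± 21.1 RPKM, and Tfpi, an inhibitor of blood coagulation, from 234 ± 36.3 to 568 ± 86.1 RPKM. The prolactin family members Prl7b1 and Prl2a1 rose 2.79-fold and 2.38-fold, and Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, rose 2.24-fold. Gstm1, Dhrs9 and Arhgap18 were also among the 10 largest named increases, at 2.50-fold, 2.32-fold and 2.17-fold. After Satb1, the largest decreases were those of the threonine dehydrogenase gene Tdh, from 6.93 ± 1.38 to 0.993 ± 0.0261 RPKM, and of Bambi, a decoy receptor of the TGF-beta family, from 16.8 ± 3.77 to 3.63 ± 1.12 RPKM.

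Decreases at day 4 also took in Bmp4, a ligand of the same family (10.1 ± 1.67 to 3.13 ± 0.512 RPKM), and Id1, a target of BMP signalling (126 ± 19.7 to 51.3 ± 10.9 RPKM). Ckmt1b, Prl5a2, Cyp4f5, Hba-a2 and Prtg completed the 10 largest named decreases, with log2 changes from -1.50 for Ckmt1b to -1.08 for Prtg. In all, 970 of 9710 genes passed the test at day 4, 693 higher and 277 lower, and 45 of them changed at least 2-fold, 30 higher and 15 lower. The count was 505 with only the 8 day-4 libraries in the model and 1978 with array weights. All 4 knockdown libraries lay on the same side of all 4 controls for 13% of genes, where chance gives 2.86%. The balance of directions depended on scaling: with median ratio scaling 746 genes were higher and 640 lower, and with quantile normalization 712 were higher and 697 lower. Without day-4 knockdown 4 the counts were 412 higher and 340 lower, and without both that library and day-4 control 3 they were 612 higher and 394 lower.

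Among the fixed lists at day 4, the TS stem state list fell, with 5 of 16 tested members lower and 1 higher (limma camera, Benjamini-Hochberg adjusted p = 1.99e-05, and adjusted p = 0.477 with an estimated correlation). Eomes, a T-box factor required for trophoblast stem cells, fell from 20.7 ± 1.27 to 12.4 ± 1.94 RPKM along with Bmp4 and Id1, while the receptor gene Lifr rose from 9.09 ± 2.25 to 14.7 ± 1.34 RPKM. The prolactin list rose, with 7 of 10 members higher and Prl5a2 lower (camera adjusted p = 0.000564, and adjusted p = 0.477 with an estimated correlation). Prl7a3 went from 174 ± 36.8 to 337 ± 39.5 RPKM. The giant cell list rose with 7 of 17 members higher and 0 lower, among them Igf2, Ctsl, Cts7 and Grn (camera adjusted p = 5.24e-05, and adjusted p = 0.477 with an estimated correlation). In the steroid list 4 of 8 members were higher, Cyp11a1, Hsd17b2 and Fdx1 among them, and Hsd3b2 was lower (camera adjusted p = 0.0238, and adjusted p = 0.556 with an estimated correlation). Adjusted over the list alone, the members higher and lower were 1 and 7 for the stem state, 8 and 1 for prolactins, 10 and 0 for giant cells, and 5 and 1 for steroid synthesis.

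Shifts in further lists at day 4 were also called by camera. The mitosis list was lower as a set with 0 of 21 members called (camera adjusted p = 0.00482, and adjusted p = 0.556 with an estimated correlation), and its lowest p belonged to Plk1, at 28.6 ± 5.18 and 22.2 ± 2.38 RPKM. DNA replication was lower with 2 of 24 members called, Uhrf1 and Ccne1 (camera adjusted p = 0.0297, and adjusted p = 0.567 with an estimated correlation). The BMP and TGF-beta list was lower with 2 of 10, Bambi and Id1 (camera adjusted p = 0.0297, and adjusted p = 0.477 with an estimated correlation). Cholesterol synthesis was lower with 2 of 21, Stard4 and Dhcr24 (camera adjusted p = 0.00415), as was the stress response with 2 of 18, including Chac1 (camera adjusted p = 0.0238). Both had adjusted p = 0.556 with an estimated correlation. Ribosomal proteins were lower with 0 of 23 members called (camera adjusted p = 0.0027, and adjusted p = 0.567 with an estimated correlation). Of 18 fibroblast markers 16 were under 1 RPKM and not tested, such as Col1a1 (mean 0.0161 RPKM) and Vim (0.151 RPKM), and the other 2, Fn1 and Pdgfra, rose, Fn1 from 1.91 ± 0.336 to 4.24 ± 1.70 RPKM (camera adjusted p = 0.0238, and adjusted p = 0.477 with an estimated correlation).

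The other 9 lists were not called at day 4. Their camera adjusted p was 0.179 for syncytiotrophoblast, 0.0814 for FGF and ERK, 0.331 for p53, 0.687 for interferon, 0.971 for hypoxia, 0.23 for epithelial junction, 0.179 for imprinted genes, 0.98 for endothelial and blood markers and 0.285 for housekeeping genes. Single members still passed the gene test, such as the ERK phosphatase gene Dusp6 (log2 change -0.84), the connexin gene Gjb3 (-0.70), Phlda2 (-1.01), Vegfa (0.83), Krt8 (0.66), Cdh5 (0.83) and Hba-a2 (-1.11). Leaving out a single library ended 7 of these list calls. The adjusted p became 0.0819 for steroid synthesis without control 1 and 0.0600 without knockdown 1, 0.0927 for BMP without knockdown 4, and 0.239 for ribosomal proteins without control 3. It became 0.344 for the stress response without control 3 and 0.0580 without knockdown 2, 0.0913 for cholesterol synthesis without control 3 and 0.0519 without knockdown 2, and 0.0592 for fibroblast markers without control 3 and 0.0547 without knockdown 1. For DNA replication it became 0.0819, 0.0781 and 0.0913 without controls 1, 2 and 3, and 0.0780 without knockdown 3. With median ratio scaling the BMP list had an adjusted p of 0.0756, and FGF and ERK was called without control 1 (0.0333) or knockdown 1 (0.0247).

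By fry, which does not compare a list with other genes, several lists called by camera at day 4 were not called. Its adjusted p was 0.0825 for steroid synthesis, 0.413 for DNA replication, 0.344 for cholesterol synthesis, and 0.371 for each of mitosis, the stress response and ribosomal proteins. Imprinted genes were called by fry alone (higher, adjusted p = 0.0168).

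Day-4 control 3 stood apart from its group: 3.37% of its reads fell on ribosomal protein genes against 2.49% to 2.62% in the other day-4 controls, and its mean correlation with them was 0.964. In the day-4 knockdown group, library 4 had the highest ribosomal share, at 2.97%. Without both libraries, the stem state list had 1 member higher and 6 lower at day 4, prolactins 5 and 1, giant cells 5 and 0, and steroid synthesis 4 and 1.

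The comparison at day 10 asked what had changed after the longer loss of Satb1. Hspb1 rose from 2.54 ± 0.689 to 56.7 ± 10.4 RPKM (SD, n = 4; log2 change 4.03 ± 0.20 SE; limma, Benjamini-Hochberg adjusted p = 3.75e-10). Placental hormone genes of the prolactin family rose with it: Prl7a3 from 215 ± 63.8 to 1442 ± 293 RPKM, Prl2a1 from 20.9 ± 4.31 to 171 ± 54.5 RPKM, and Prl4a1, Prl7b1 and Prl5a1 by 9.14-fold, 8.97-fold and 6.98-fold. Cyp11a1 rose from 5.94 ± 1.89 to 57.7 ± 14.8 RPKM, and the keratin gene Krt19 from 9.41 ± 3.14 to 80.6 ± 13.6 RPKM. Ceacam3 rose 8.94-fold, and Ctsj, a placental cathepsin, went from 0.223 ± 0.0605 to 8.22 ± 3.21 RPKM. The prolactin, cathepsin and Ceacam genes belong to families of close paralogs, whose reads the counting may have shared.

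Decreases at day 10 were again led by Satb1, Tdh and Bambi, with Tdh at 6.67 ± 2.16 RPKM in the controls and 0.213 ± 0.101 RPKM in the knockdown libraries. Fabp3 fell from 561 ± 151 to 174 ± 71.1 RPKM and Rbp7 from 66.3 ± 14.9 to 19.6 ± 6.97 RPKM. Pqlc3 fell from 124 ± 20.1 to 35.5 ± 10.7 RPKM, the metalloprotease gene Adam15 from 9.61 ± 1.75 to 2.29 ± 0.788 RPKM, Cyp4f5 from 4.17 ± 0.394 to 0.635 ± 0.185 RPKM, and Psmb9, a subunit of the immunoproteasome, from 3.75 ± 0.682 to 0.514 ± 0.196 RPKM. At this day 3468 of 9710 genes passed the test, 2353 higher and 1115 lower, and 412 changed at least 2-fold, 316 higher and 96 lower. The groups did not overlap for 43.8% of genes, where chance gives 2.86%. The direction split again depended on scaling, with 2135 higher and 1966 lower under median ratio scaling and 1923 higher and 2132 lower under quantile normalization.

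The stem state list fell at day 10, with 10 of 16 members lower and 2 higher (limma camera, Benjamini-Hochberg adjusted p = 3.59e-06, and adjusted p = 0.229 with an estimated correlation). Eomes fell from 18.5 ± 2.59 to 7.06 ± 1.80 RPKM, the Kruppel-like factor gene Klf5 from 32.3 ± 4.98 to 12 ± 3.37 RPKM, Id1 from 103 ± 18.1 to 33.5 ± 11.6 RPKM and Bmp4 from 7.45 ± 2.09 to 1.89 ± 0.711 RPKM, whereas Lifr rose from 9.81 ± 0.844 to 18.7 ± 0.577 RPKM. Of the 21 listed prolactin members, 10 were tested. The list rose with 9 of these higher (camera adjusted p = 6.15e-07, and adjusted p = 0.229 with an estimated correlation). Prl5a2 fell from 8.20 ± 1.51 to 2.52 ± 0.761 RPKM. The giant cell list rose with 15 of 17 members higher and 0 lower (camera adjusted p = 2.33e-08, and adjusted p = 0.229 with an estimated correlation). Its members included Igf2, a fetal growth factor gene, from 26.0 ± 2.19 to 85.8 ± 4.35 RPKM, Serpine1, an inhibitor of plasminogen activators, from 24.5 ± 3.28 to 90.4 ± 22.9 RPKM, and Cgm4 and Cited2. Steroid synthesis rose with 7 of 8 members higher and Hsd3b2 lower (camera adjusted p = 7.51e-06, and adjusted p = 0.229 with an estimated correlation). Star, which carries cholesterol into mitochondria, rose from 1.40 ± 0.171 to 9.71 ± 2.03 RPKM, Fdxr, which reduces the ferredoxin that serves Cyp11a1, from 8.36 ± 2.00 to 24.1 ± 4.04 RPKM, and Hsd17b2 from 10.6 ± 3.07 to 44.4 ± 10.1 RPKM.

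Genes of cell division fell at day 10. The mitosis list had 13 of 21 members lower and 0 higher (camera adjusted p = 6.15e-07, and adjusted p = 0.27 with an estimated correlation), including Top2a (79.1 ± 8.22 to 46.5 ± 9.39 RPKM), Birc5, Cdc20 and Bub1b. DNA replication had 10 of 24 lower and 2 higher (camera adjusted p = 0.000273, and adjusted p = 0.398 with an estimated correlation), with the cyclin gene Ccne1 falling from 64.0 ± 7.69 to 33.1 ± 3.44 RPKM. The p53 and cell cycle arrest list rose with 9 of 16 higher and 0 lower (camera adjusted p = 0.00117, and adjusted p = 0.27 with an estimated correlation). Its largest change was that of Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, from 46.1 ± 11.4 to 208 ± 48.4 RPKM. Btg2, Tp53inp1 and Plk3 rose by 0.78, 0.87 and 0.73 on the log2 scale. Cdkn1a, the best-known p53 target of the list, was at 14.3 ± 2.33 and 19.3 ± 3.26 RPKM and did not pass the test (adjusted p = 0.0578). Ribosomal proteins fell with 7 of 23 lower (camera adjusted p = 3.59e-06, and adjusted p = 0.408 with an estimated correlation), and their share of reads was 1.88% to 2.28% in the knockdown libraries and 2.41% to 2.86% in the controls. The number of lower members depended on scaling: 21 ribosomal proteins with median ratio scaling and 16 with libraries brought to the same sum, and 15 of DNA replication with quantile normalization. Mitochondrial reads made up 1.40% to 1.66% in the knockdown libraries and 1.23% to 1.43% in the controls at day 10, and 1.21% to 1.42% and 1.00% to 1.30% at day 4.

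Adjusted over the list alone, the members higher and lower at day 10 were 2 and 11 for the stem state, 9 and 1 for prolactins, 17 and 0 for giant cells, 7 and 1 for steroid synthesis, 0 and 17 for mitosis, 2 and 10 for DNA replication, 11 and 1 for p53, and 0 and 10 for ribosomal proteins. Both tested fibroblast markers of the 18 rose, Fn1 from 1.6 ± 0.325 to 12.5 ± 4.75 RPKM and Pdgfra from 2.01 ± 0.548 to 6.98 ± 1.94 RPKM (camera adjusted p = 0.00588, and adjusted p = 0.229 with an estimated correlation). Of the 3 endothelial and blood markers tested (of 16 listed), Cdh5 and Cd68 rose and Hba-a2 fell, and the list was not called (camera adjusted p = 0.478). No single left-out library ended any of the 9 list calls at day 10, and fry called the same 9. By fry alone, BMP and TGF-beta was lower (adjusted p = 0.0341), and epithelial junction (0.00174), imprinted genes (1.2e-06) and endothelial and blood markers (0.000724) were higher. Of the imprinted genes that rose, Igf2 also belongs to the giant cell list and Cdkn1c to the p53 list. The imprinted call is thus not fully separate from those lists. With day-4 control 3 and day-4 knockdown 4 left out of the shared estimate of spread, 19 mitosis members and 18 ribosomal proteins were lower at day 10.

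**Figure D2:**
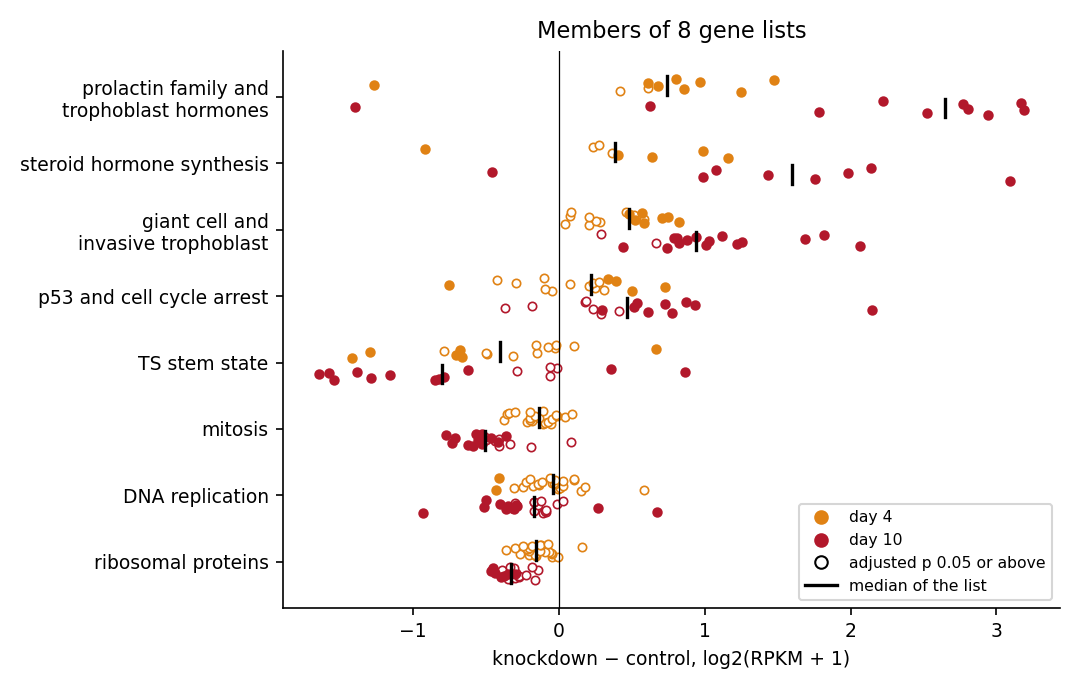
Log2 change of RPKM + 1 between knockdown and control for the tested members of 8 lists, at day 4 (orange) and day 10 (red); filled points passed an adjusted p of 0.05 and black bars are list medians. At day 10, 9 of 10 prolactin members and 15 of 17 giant cell members were called higher, and 13 of 21 mitosis members lower.

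The remaining lists were not called at day 10. The camera adjusted p was 0.26 for syncytiotrophoblast, 0.085 for BMP and TGF-beta, 0.862 for interferon, 0.337 for epithelial junction, 0.106 for imprinted genes and 0.168 for housekeeping genes. It was 0.337 for FGF and ERK, 0.754 for the stress response, 0.754 for cholesterol synthesis and 0.478 for hypoxia, lists in which the sign of the median or the balance of calls changed with scaling. Members of these lists moved in opposite directions. The keratin gene Krt8 rose from 530 ± 46.8 to 1144 ± 32.9 RPKM and Krt7 from 27.1 ± 9.74 to 120 ± 40.8 RPKM. Gjb3 fell from 76.8 ± 3.01 to 29.5 ± 4.23 RPKM, the glucose transporter gene Slc2a3 from 62.4 ± 11.9 to 25.7 ± 6.91 RPKM, and the ERK antagonists Spry1, Spred1 and Dusp6 by 1.01, 0.98 and 0.92 on the log2 scale, while Vegfa rose by 1.44 and Xbp1 by 0.63. Among imprinted genes Igf2, Cdkn1c and Peg3 rose and Phlda2 fell. Of the housekeeping genes, Eef1a1 fell by 0.54 and Actb rose by 0.44 on the log2 scale.

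**Figure D3:**
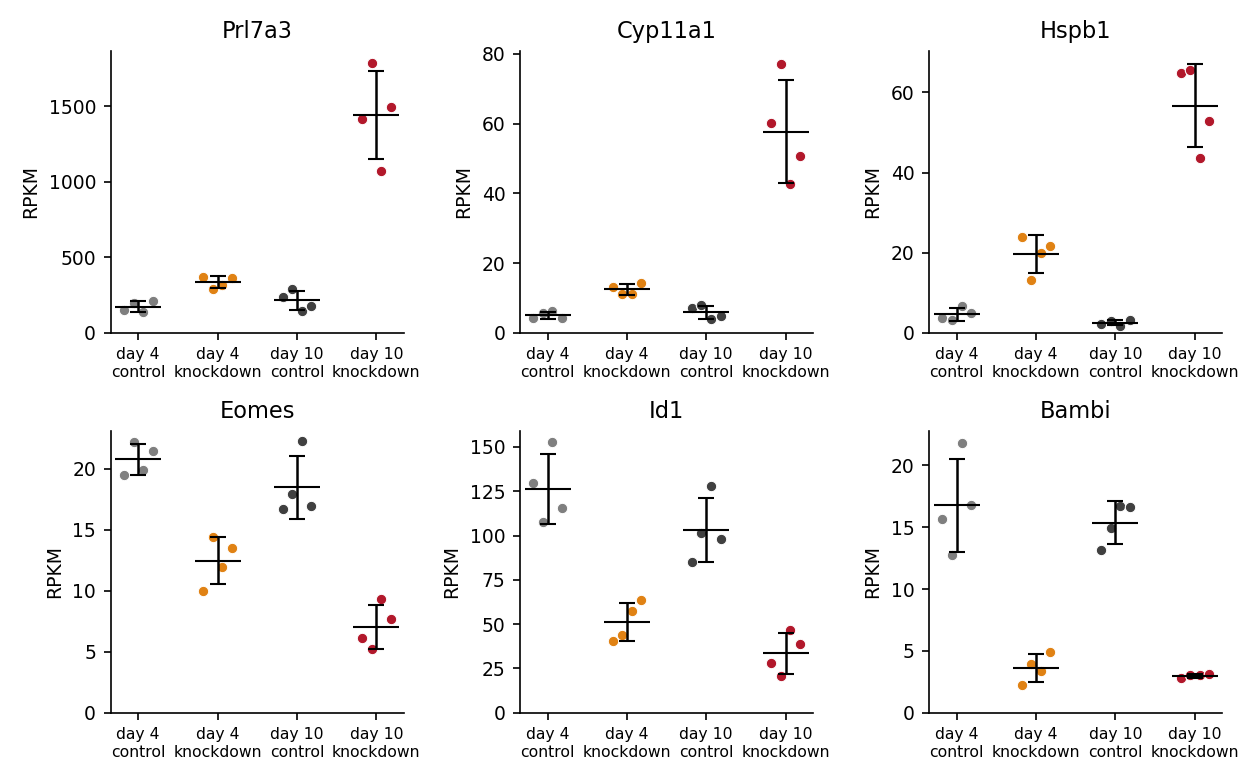
RPKM of 6 genes in the 16 libraries, by group; points are libraries, bars are the mean and SD of 4, and each panel has its own axis from 0. Prl7a3, Cyp11a1 and Hspb1 were higher in the knockdown libraries at each day, and Eomes, Id1 and Bambi lower.

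Next, the effects of the knockdown at the 2 days were compared. The genes that moved at day 4 moved the same way at day 10: of 970 genes called at day 4, 967 had the same sign at day 10, and none was called in opposite directions. Plet1, Krt7, Dhrs9 and Tfpi were called higher at each day, and Tdh, Bambi, Bmp4 and Id1 lower. The days shared 658 higher genes, where independent lists would share 168, and 251 lower genes, where independent lists would share 31.8. Both contrasts use the same estimate of spread per gene, which can favour the same genes in each list. The numbers for independent lists are thus a low baseline. Across the 9710 genes the log2 changes had a Pearson correlation of 0.816 and a Spearman correlation of 0.769. The effects were measured against different control libraries, and genes are not independent replicates, so no p is given.

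**Figure D4:**
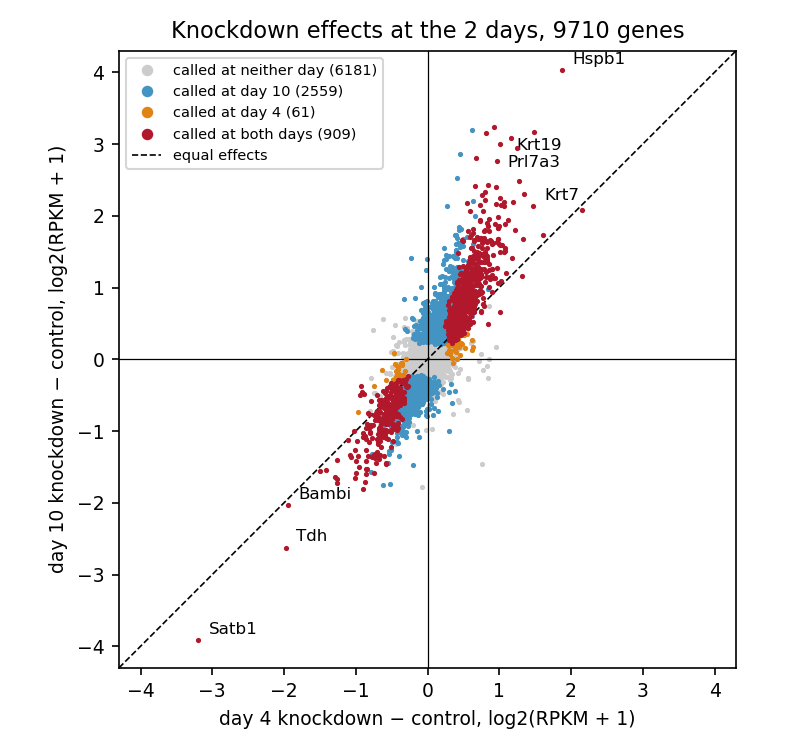
Log2 change of RPKM + 1 with knockdown at day 4 (x axis) and day 10 (y axis) for 9710 genes; colours give the days at which a gene was called, and the dashed line marks equal effects. Of the genes called at day 4, 967 had the same sign at day 10, and the correlation across genes was 0.816.

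Whether the effect itself differed between days was tested as a difference of effects. The largest gains of named genes at day 10 over day 4 were those of Prl4a1 (2.58 ± 0.33 SE on the log2 scale; limma, Benjamini-Hochberg adjusted p = 0.00046), Ctsj (2.40 ± 0.23), Ceacam3 (2.34 ± 0.23), Hspb1 (2.16 ± 0.29) and Prl5a1 (2.13 ± 0.23). Prl4a1, for example, was at 5.55 ± 1.35 and 8.90 ± 0.990 RPKM in the control and knockdown libraries of day 4 but at 5.30 ± 1.93 and 58.2 ± 23.5 RPKM at day 10. Star showed a difference of 1.87 ± 0.19, Cyp11a1 of 1.93 ± 0.27 and Cdkn1c of 1.42 ± 0.27. Differences towards lower values were Wnk3 (-1.27 ± 0.25), Fxyd4 (-0.94 ± 0.22), Nup210 (-0.68 ± 0.16) and Dcst2 (-0.66 ± 0.16). These 4 were called in that direction against 119 called higher, and all 119 were higher at day 10 with a larger change than at day 4. The balance depended on the method, with 708 higher and 110 lower with array weights, 119 higher and 51 lower under median ratio scaling and 107 higher and 51 lower under quantile normalization. All 123 were among the genes called at day 10, and 60 were also called at day 4.

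By camera the lists whose change was more positive at day 10 were prolactins (adjusted p = 1.75e-12), steroid synthesis (3.68e-12), giant cell (4.63e-10), p53 (3.21e-06), fibroblast markers (0.00115), cholesterol synthesis (0.00187), imprinted genes (0.0128) and endothelial and blood markers (0.0452). Lists whose change was more negative were mitosis (1.96e-06), ribosomal proteins (0.000224), DNA replication (0.000713) and stem state (0.000943). These 4 were not called by fry, with adjusted p of 0.241, 0.395, 0.301 and 0.301, nor was cholesterol synthesis (fry adjusted p = 0.221). Fry called the other lists named here. None held with an estimated correlation, where the lowest were adjusted p = 0.0553 for prolactins and steroid synthesis. Those for giant cell, p53, fibroblast markers and imprinted genes were adjusted p = 0.102, and for endothelial and blood markers adjusted p = 0.13. For mitosis, stem state, DNA replication, cholesterol synthesis and ribosomal proteins they were adjusted p = 0.286, 0.348, 0.41, 0.49 and 0.532 with an estimated correlation. Adjusted over the list alone, 8 prolactin, 8 steroid, 8 giant cell and 6 p53 members had a more positive change at day 10, which for Hsd3b2 of the steroid list was a smaller fall. Cholesterol synthesis was lower at day 4 and not called at day 10. A more positive difference can also arise from lower values in the day-10 controls. For p53 the median difference was 0.36 on the log2 scale, and the median change from day-4 to day-10 controls was -0.36. For cholesterol synthesis these were 0.21 and -0.18, against 1.69 and 0.19 for prolactins. The p53 and cholesterol differences thus cannot be read as a rise in the knockdown libraries from day 4 to day 10.

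The count of 123 moved by more than 1.5 times when some libraries were left out. It was 227 without day-4 control 3, 77 without day-4 control 4, 58 and 65 without day-4 knockdown 2 and 3, 78, 58 and 59 without day-10 controls 1, 3 and 4, and 60, 59, 274 and 80 without day-10 knockdown 1, 2, 3 and 4. The call of Fxyd4 was kept only without day-4 control 3, day-4 knockdown 3, day-10 control 4 or day-10 knockdown 3, and without any other library its adjusted p was 0.0545 to 0.114. Nup210 was kept only without day-4 control 3, day-4 knockdown 1, day-10 control 2 or day-10 knockdown 3 (0.0540 to 0.114 otherwise), and Dcst2 without these or day-10 control 1 (0.0556 to 0.120 otherwise). The call of endothelial and blood markers ended without day-4 controls 1, 2, 3 or 4, day-4 knockdown 1 or 4, day-10 control 3 or 4, or day-10 knockdown 1 (adjusted p 0.0528 to 0.0769), with median ratio scaling (0.0663) and with a pseudocount of 0.1 (0.0696). Hypoxia (0.0136) and housekeeping genes (0.0284) were called without day-4 control 3, and the stress response (0.0163) without day-4 control 2.

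The controls of both days were compared to show the change between days without knockdown, in which culture time and any batch go together. Fewer genes passed this test, 49 of 9710, all lower at day 10, and 0 changed by 2-fold or more. The microtubule-binding protein gene Mtcl1 fell from 14.2 ± 0.876 to 7.40 ± 1.27 RPKM (limma, Benjamini-Hochberg adjusted p = 0.00104) and the laminin gene Lama5 from 33.8 ± 4.22 to 18.4 ± 2.39 RPKM (adjusted p = 0.0164). Cdkn1a fell from 26.2 ± 4.24 to 14.3 ± 2.33 RPKM, the stress-induced cytokine gene Gdf15 from 3.92 ± 1.18 to 1.83 ± 0.401 RPKM, and Il17rd, an FGF antagonist gene, from 3.34 ± 0.603 to 1.54 ± 0.253 RPKM. The p53 list was lower with 3 of 16 members called (camera adjusted p = 8.95e-06, and adjusted p = 0.552 with an estimated correlation). Hypoxia (camera adjusted p = 0.00543) was lower with 0 of 20 members called, and FGF and ERK (0.0347) with 1 of 13. They had adjusted p = 0.926 and adjusted p = 0.588 with an estimated correlation. The stem state and prolactin lists were not called between the controls (camera adjusted p = 0.163 and 0.133). At an unadjusted p under 0.05 there were 1746 genes, and the groups did not overlap for 8.62%, where chance gives 2.86%.

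With only the 8 control libraries in the model, 0 genes passed. The direction in the controls depended on the method and on scaling, with 1 gene higher and 78 lower by limma voom on the recovered reads, 45 higher and 126 lower under median ratio scaling, 28 and 102 under quantile normalization, and 10 and 444 with libraries brought to the same sum. The count was 1, 19 and 24 without day-4 controls 1, 3 and 4, 24 without day-4 knockdown 3, 1, 2, 103 and 1 without day-10 controls 1, 2, 3 and 4, and 26, 26, 24 and 12 without day-10 knockdown 1, 2, 3 and 4. Mtcl1 kept its call in each case, but Lama5 lost it without day-4 control 1 or day-10 control 1, 2 or 4 (adjusted p 0.0505 to 0.110). Cdkn1a lost it without day-4 control 1, 2 or 3, day-10 control 1, 2 or 4, or day-10 knockdown 4 (0.0502 to 0.156), Gdf15 without day-4 control 1, 3 or 4 or the same day-10 libraries (0.0502 to 0.136), and Il17rd without day-4 control 1 or 3 or day-10 control 1, 2 or 4 (0.0502 to 0.126). The hypoxia call ended without day-4 control 3 (0.0940), and FGF and ERK without day-4 control 2 (0.0969) or 4 (0.0958) or with median ratio scaling (0.0603). Stem state (0.0421, lower) and prolactins (0.00138, higher) were called without day-10 control 3, and cholesterol synthesis (lower) without day-4 control 2 (0.00171) or day-10 control 4 (0.0125) and with the replicate number as a block (0.0238). Day and any batch of library preparation cannot be told apart in this comparison.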

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

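For day-4 control 3, the tests of row length and of a sample swap were chosen only after the result was seen. So was the comparison of effect sizes, meant as a test of spread, for the larger response at day 10. The Satb1 level was also considered only then, and no test of it was run. A sample lay far from the other 3 of its group in 8 of 192 groups tested, of which 5 were among 156 groups of named genes, and chance gives about 1 in 20. Day-4 control 3 was far in its share of ribosomal protein reads (3.37% against 2.49% to 2.62%) and in its slope of expression on row length (-0.147 against 0.0464 to 0.0509). The same library was low in Wnk3 (2.42 RPKM against 4.88 to 5.10 RPKM). Day-4 knockdown 1 was low in Satb2 (3.27 against 4.22 to 4.32 RPKM), and day-10 knockdown 3 in Krt19 (60.4 against 85.4 to 89.3 RPKM). Day-10 control 3 was high in Nup210 (7.08 against 5.10 to 5.15 RPKM), day-4 control 1 was high in Mtcl1 (15.5 against 13.7 to 13.9 RPKM), and day-4 control 4 was low in Cdkn1a (19.9 against 27.5 to 28.8 RPKM).

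The knockdown effect differed between days for 123 genes (limma, Benjamini-Hochberg adjusted, two-sided). Of the named genes, the effect on the log2 scale was more positive at day 10 by 2.16 for Hspb1, 1.69 for Prl7b1, 1.21 for Tfpi, 1.69 for Prl2a1, 1.93 for Cyp11a1, 0.83 for Arhgap18, 2.58 for Prl4a1, 2.34 for Ceacam3, 2.00 for Krt19, 2.40 for Ctsj, 2.13 for Prl5a1 and 1.80 for Prl7a3. It differed by -1.27 for Wnk3, -0.94 for Fxyd4, -0.68 for Nup210 and -0.66 for Dcst2. Lists that differed by camera, with their adjusted p, were stem state (0.000943), prolactins (1.75e-12), giant cell (4.63e-10), steroid synthesis (3.68e-12), DNA replication (0.000713), mitosis (1.96e-06), p53 (3.21e-06), cholesterol synthesis (0.00187), imprinted genes (0.0128), fibroblast markers (0.00115), endothelial and blood markers (0.0452) and ribosomal proteins (0.000224). None of the 12 was called with an estimated correlation.

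Other splits of the same samples were counted for each number of genes. At day 4, 1 of 35 splits, the real grouping, gave 970 genes, and the highest other gave 310. At day 10, 1 of 35 gave 3468, and the highest other gave 0. For the controls of both days, 1 of 35 gave 49, and the highest other gave 1. In the model of all 16 libraries no other split reached these counts, and 1 of 35 is the smallest share possible. Splits that mix the groups put real effects into the spread and so lower their own counts. With only the 8 control libraries in the model, 0 genes passed for the real grouping. The splits cover chance among these libraries, which may be technical replicates, and not chance between cultures. For the difference between days, 2 of 100 regroupings of day within each treatment gave as many as 123 genes, the real grouping included, and the highest other gave 1008. That regrouping kept all knockdown libraries at their real day and exchanged day-4 controls 3 and 4 with day-10 controls 1 and 2, while the next largest gave 89 and the median was 0. Because the knockdown libraries keep their real day, their change with day stays in that contrast, which is thus not free of the effect tested. That regrouping also sets controls 1 and 2 of each day against controls 3 and 4, and moves day-4 control 3, which stood apart from its group. Why it called more genes was not tested.

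Day-4 control 3 stood apart from its group. Row length explained 11.1% of the variance of its deviation, which argues against length bias as the whole cause, and its mean correlation with its group was 0.964 as deposited and 0.966 with the length trend removed. Its Satb1 level of 89.4 RPKM, above every knockdown library, argues against a swap with a knockdown library. The correlation of its deviation with the day-10 knockdown effect across genes was -0.0167, which argues against more or fewer differentiated cells of the kind seen after knockdown. RNA quality and library preparation stay open, as no value here tested them.

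The response was larger at day 10 than at day 4. The day-10 knockdown libraries were the shallowest (33.1 to 50.4 M reads, against 50.7 to 56.7 M in the day-4 knockdown), which argues against more calls through more depth, and the ratio of called genes was 3.61 with reads thinned to the lowest total (3.58 as deposited). Among genes called at day 4 the median ratio of the day-10 to the day-4 log2 change was 1.46, and 82.0% of them were larger at day 10. These values describe the size of the changes and do not measure spread. In the model of all 16 libraries a gene has the same standard error at each day. Wider spread among the day-4 libraries therefore could not lower the calls of that day alone through the standard error. The 95% bootstrap interval of the median ratio over genes was 1.42 to 1.51 (2000 draws). It treats genes as independent and leaves out the spread between libraries, so the uncertainty of the ratio was not measured. Less Satb1 was left at day 10 (6.0% of the control level). Between days this cannot be told apart from the longer time, because both go with day. Within a day, whether libraries with less Satb1 showed larger responses was not tested. A batch of library preparation by day stays open as well, since the labels give none.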

How the results depend on the processing

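The sum of rows, every row tested, voom, removal of the row length trend, thinned reads, and leaving out both day-4 control 3 and day-4 knockdown 4 were tests chosen after the data were seen. Of the alternatives for the main results, 177 kept their direction and their side of the threshold, or lay within 1.5 times the count. Another 34 were weaker and 12 were stronger. Satb1 remained lower at each day in all of its alternatives, and the correlation of the effects ran from 0.765 to 0.889. No gene called in both the reported analysis and an alternative changed sign, except that signs were not compared where every row was tested. Some settings, such as only the 8 libraries compared or no mean-variance trend, leave the log2 changes as reported, so their signs could not differ.

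At a mean of at least 5 RPKM, where fewer genes were tested, 634 genes passed at day 4, 2250 at day 10, 41 for the difference and 20 between the controls. At a minimum of 2-fold, a stricter rule, 45, 412, 65 and 0 passed. Array weights gave 1978 at day 4, 818 for the difference and 436 between the controls, and the cause was not tested. With only the 8 libraries compared, 505 passed at day 4, 4603 at day 10 and 0 between the controls. The model of all 16 libraries shares its estimate of spread per gene between all groups. The mean correlation of a library with its own group was 0.964 to 0.989 at day 4 and 0.989 to 0.994 at day 10. With only its own 8 libraries each comparison took its own spread. The count then fell at day 4 (970 to 505) and rose at day 10 (3468 to 4603). Those fits also estimate spread from fewer libraries, so how far unequal spread alone accounts for the counts was not tested. Libraries brought to the same sum gave 286 for the difference and 454 between the controls. Without day-4 control 3 and day-4 knockdown 4 the difference had 312 genes. Between the controls the count was 171 with median ratio scaling, 130 with quantile normalization, 79 with voom, 20 with every row tested, 20 with the row length trend removed and 15 with no filter, and the cause was not tested.

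Leaving out each library gave 719 to 1317 genes at day 4, 2638 to 4293 at day 10, 58 to 274 for the difference and 1 to 103 between the controls. Of the list tests at both days, 20 were called by camera, 19 by fry (not all the same lists) and 0 with an estimated correlation. The change of Satb2 at day 4, which did not pass the test, ran from -0.20 to 0.0024 on the log2 scale, the latter without day-4 knockdown 1. Among named genes, 1172 alternatives left the result in place, 59 ended a call and 1, that of Satb2, reversed the sign.

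The labels do not say that replicate numbers pair the libraries, and the values left this unclear: the correlation of control and knockdown deviations with the same number ran from -0.44 to 0.45, and 3 of 4 at day 10 were above 0. With the number as a block the counts were 1020, 3453, 144 and 44, of which 32 between the controls were shared. Depth set a limit for low genes, as 1 RPKM stood for 33.1 reads per kilobase in the shallowest library.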

Other observations

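The test of neighbouring genes was planned before its result was seen, but the median and number of the splits compared with it were chosen after. Satb1 organises chromatin, and a hypothesis was that neighbouring genes change together after its loss. Adjacent genes, in the order of the assembly GRCr8, had day-10 effects with a correlation of 0.0936 over 8261 pairs, above the highest of 1000 permutations of positions (0.0477). Splits of the libraries within the day-10 groups, where knockdown is not compared with control, gave correlations of 0.0141 to 0.113 with a median of 0.0448. Of the 6 splits, 1 reached the value of the knockdown, and it lay within the knockdown group. The highest split within the control group gave 0.0592. Knockdown libraries may hold different shRNAs, so a split among them may itself compare knockdowns. Knockdown effects from 2 against 2 libraries gave a median of 0.0925 and never fell below 0.0746. With so few splits, regional regulation by Satb1 cannot be told apart from covariation of neighbours in any comparison of these libraries. The hypothesis stays open.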
